A study of Mus musculus with 12 samples.

How the data were processed

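Total RNA (100 ng) from 12 cultures of mouse embryonic fibroblasts was labelled with Cy3 together with spike-in RNA and hybridised by the authors to Agilent one-colour 4x44K arrays, 1 array per culture. Per the file headers, each scanner file holds spot intensity on a linear scale from Feature Extraction 10.5.1.1, background-subtracted and detrended within the array and not normalised between arrays. The deposited value table holds log2 intensity; how it was normalised and filtered is not stated. All results rest on the scanner files, and the deposited table was used as an alternative.

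Groups and days came from the labels, with 3 cultures in each of 4 groups (rescue_sparse, rescue_dense, KO_sparse, KO_dense). The replicate number is the experimental day, so that 1 culture of every group shares a day. Whether the day pairs the arrays was checked by the correlation, across genes, of deviations from the group means: 11 of 18 pairs of arrays of the same day were above 0.1 (range -0.038 to 0.292). The day entered as a replicate block only as an alternative, since the labels name the days and no block. The headers give 5 slides. The 2 densities of a line and day always shared a slide, while the 2 lines shared 1 slide only, on day 2. For the other days line and slide cannot be told apart. Fits with the slide as a block do not part them either. There the mean difference between the lines comes from the day 2 slide alone, with 1 culture per group, and only the density responses use all slides.

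Of 43379 spots that are not controls, those flagged by the scanner software as not uniform or as population outliers (79 to 265 per array) were set to missing, and no spot of the arrays was saturated. Log2 processed signals of a probe printed 10 times (245 of 41174 probes) were averaged, and the 75th percentile of all probes of an array (294 to 1594 intensity units) was subtracted. Probes were named by the RefSeq transcript given in the files and the supplied list of gene symbols (mouse assembly GRCm38.p6); 24375 had 1 gene, and 16799, with other kinds of identifier or none in that list, were left out. No sequence or position of a probe was at hand. Probes well above background on all 3 arrays of at least 1 group were kept (25931, of which 18158 with a gene), and the one with the highest mean over the 12 arrays stood for its gene, which gave 12438 of the 17016 genes on the array. Of 4467 genes with several kept probes, 21, 41, 25, 21 and 4 had probes called in opposite directions in the 5 comparisons in the order of the report.

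Genes were tested with limma 3.58.1 in R 4.3.3 (files read with data.table, version 1.17.8): 1 mean for each of 4 groups, moderated variances (8 residual and 3.58 prior degrees of freedom) and Benjamini-Hochberg adjustment over all genes within each of 5 comparisons, with an adjusted p threshold of 0.05. The comparisons were KO minus rescue in sparse and in dense cells, dense minus sparse in rescue and in KO cells, and the interaction (dense minus sparse in KO, minus the same in rescue). With 3 against 3 cultures a rank or permutation test could not go below 0.1, so only the model across genes is used. Where a gene was not well above background on any array of the dimmer group, the lower bound compares the mean of the brighter group with the mean, over the arrays of the dimmer group, of the higher of 2 signals: the lowest signal among the array's probes well above background, and the probe's own. Of the changed genes 786, 843, 208 and 58 had 1 such group in the first 4 comparisons.

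The 23 gene lists were focal adhesion and integrin components, collagens and matrix proteins, matrix proteases and inhibitors, SRF and actomyosin genes, YAP and TEAD targets, cell cycle and mitosis, CDK inhibitors and p53 targets, cholesterol synthesis and uptake, LXR targets and sterol efflux, sphingolipid metabolism, caveolae, FOXO targets, immediate early and ERK feedback genes, interferon response, hypoxia and glycolysis, ATF4 and amino acid response, unfolded protein response, chemokines and cytokines, cadherins and junctions, Wnt targets and inhibitors, TGF-beta and BMP response, lysosome and autophagy, and 1 list that is not reported here. A second family of 9 lists held markers of cell types and sex chromosomes. Lists were tested with limma's camera (preset correlation 0.01, adjusted within each family and comparison), and beside it with an estimated correlation and with fry. Counts adjusted over the list alone use the same limma p values.

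The genes named were chosen by a rule. In each comparison, among genes with an assigned symbol that passed and whose groups did not overlap (for the interaction, that passed), the 8 largest rises and 8 largest falls were eligible, 5 and 5 for the interaction. Of each list, the 3 called members with the largest change and the called member with the largest opposite change were eligible, and the text names fewer. Ptk2, Ptk2b, Abca1 and Foxo3 were named whatever their values. The genes of the mesothelial list and the sex-linked genes in the closing section are the members of lists, and the spike-in and 28S values were looked at after the data were seen.

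Groups, comparisons, tests, lists, the naming rule and the alternatives listed next were fixed before the data were examined. These were quantile normalisation, median centring, the deposited values, no filter or a filter on all 12 arrays, keeping flagged spots, the mean of a gene's probes, a stricter adjusted p of 0.01, a 2-fold minimum, a variance trend with robust estimation, only the 6 arrays compared, the day as a replicate block, the slide as a block, and leaving out each array or day. A planned background correction (normexp, offset 50) of mean signals was not run, because the files hold no such column. Chosen after seeing the data were normexp on median signals, the slide as a random block, probes without a gene included, spike-in scaling, days 1 and 2 of the deposited table, and choosing filter and probes again in each setting. In a first run filter and probes were chosen again in every setting and 3 genes changed sign because another probe took over; only after that were genes and probes held, and both versions are reported.

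Of the deposited columns, 8 of 12 had their highest correlation with the scanner file of the same label (r = 0.98 to 0.987), while the 4 columns of day 3 had it with the array of the other line at the same density (r = 0.972 to 0.984, against 0.833 to 0.874 with their own). The group labels of the scanner files were kept, since their day 3 arrays lay with the other arrays of their line and density. Of the table's probes 13602 had no value, of which 29.7% were well above background on at least 1 array.

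The procedure was tested on simulated data with 50 genes at each of 4 known log2 changes among 12438. Genes shifted by 1 were recovered in 46, 44, 34, 46 and 10% of cases in the 5 comparisons, and those shifted by 2 in 88, 86, 74, 84 and 70%, with 3 to 6 unchanged genes called. The 1 list that was shifted was called in every comparison, and 0 of the others. The simulated noise was independent between genes, so this does not show how camera behaves when the genes of a list are correlated. Far fewer genes were changed than passed in the real data, so the recovery rates need not carry over.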

Results

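Messenger RNA was measured on 12 one-colour mouse expression arrays, 1 per culture, from 2 lines of embryonic fibroblasts. Focal adhesion kinase (FAK), the product of Ptk2, is a tyrosine kinase that acts where integrins hold the cell to the matrix. The knockout (KO) line lacks FAK, and the rescue line is a clone of such cells, DA2, that was given FAK back. Each line was seeded sparsely (410000 cells) or densely (8200000 cells) in a 10 cm dish and harvested after 24 h. The 4 groups had 3 cultures each, 1 from each of 3 experimental days, numbered 1 to 3 by day. The rescue line alone was grown with hygromycin and non-essential amino acids, so line and medium changed together. Across the 12 arrays the median spot signal was 19.5 to 84.6 intensity units, and 23152 to 26183 of 41174 probes were well above background. Replicates of a group had correlations of 0.982 to 0.992 across genes, which are not independent replicates. In a principal component analysis, the first component held 77.6% of the variance and parted the lines, and the second held 10.3% and parted the densities. Changes are log2 fold changes ± SE from a limma fit of 12438 genes, with 3 cultures per group, and a gene changed when its adjusted p was under 0.05. The number of arrays limits the precision. Where a gene was not well above background on any array of a group, its change is given as a lower bound ("at least"). This bound uses the lowest well-above-background signal of an array, or the probe's own if higher, and is not a detection limit of the probe. Its size depends on how background is handled. With normexp the sex chromosome list had a median of -1.77 between the lines in sparse cells, against -4.02 with bounds.

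Ptk2 itself was measured by 2 probes, both well above background on all 12 arrays. The brighter probe had a mean of 0.31 ± 0.21 (SD, n = 3) in sparse rescue cells, 0.36 ± 0.03 in dense rescue cells, 0.20 ± 0.15 in sparse KO cells and 0.29 ± 0.24 in dense KO cells, in log2 units relative to the array's 75th percentile. Both probes were tested in a fit of the 25931 probes well above background. On the brighter one KO minus rescue was -0.11 ± 0.19 in sparse cells (limma, adjusted p = 0.648) and -0.07 ± 0.19 in dense cells (adjusted p = 0.763). The other probe had means of 0.71 ± 0.50, -0.68 ± 0.44, -1.37 ± 0.34 and -1.61 ± 0.27 in the same order. On it KO minus rescue was -2.08 ± 0.31 in sparse cells (limma, adjusted p = 0.000167) and -0.93 ± 0.31 in dense cells (adjusted p = 0.021). The dense difference lost its call with the slide as a block (-0.53) and without rescue_dense 3 (-0.68) or KO_dense 1 (-0.80). With the slide as a block, the mean difference between the lines comes only from the 1 slide that held both, with 1 culture per group. Within the 1 slide that held both lines, the other probe differed by -1.49 in sparse and by -0.72 in dense cells. Where either probe lies relative to the deleted part of the gene is not known, so neither decides whether intact FAK mRNA was present. The related kinase gene Ptk2b (Pyk2) was higher in KO cells in the fit of genes, by 1.47 ± 0.32 in sparse cells (adjusted p = 0.00217) and by 1.86 ± 0.32 in dense cells (adjusted p = 0.000273), and its second probe by 1.88 and 1.06 in the fit of probes.

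**Figure D1:**
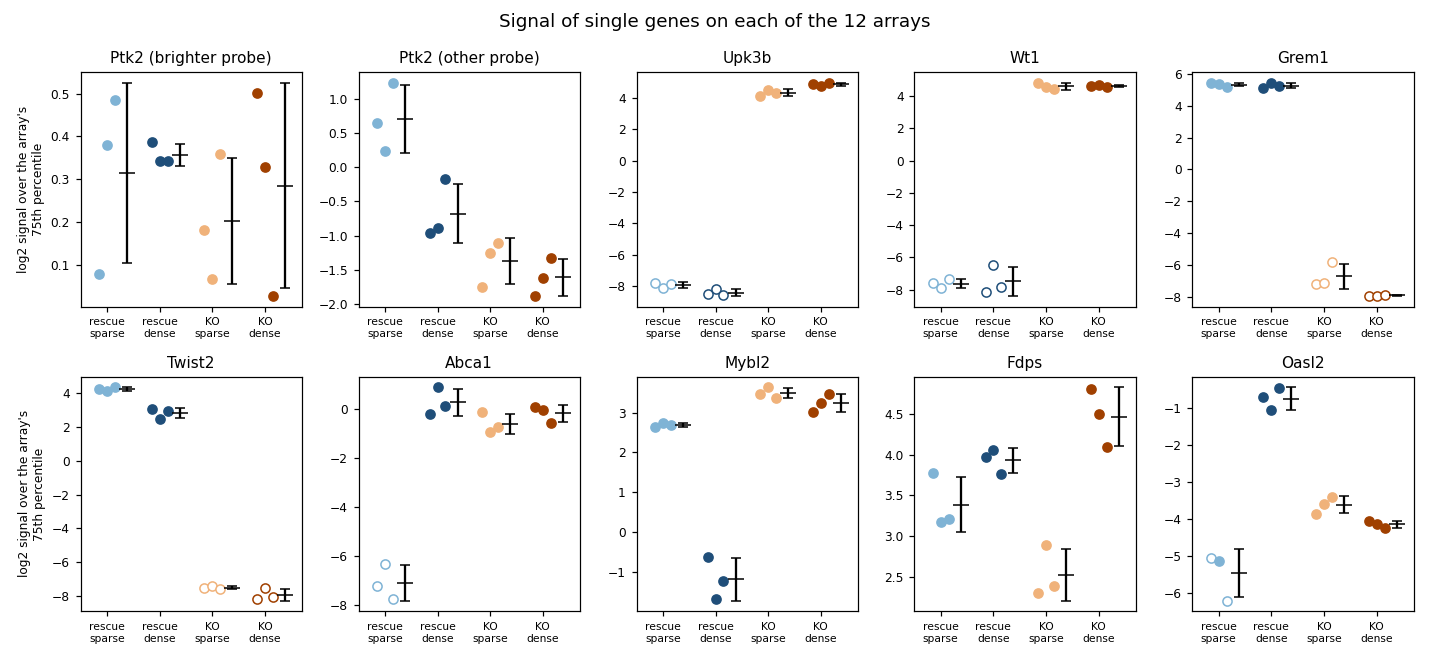
Log2 signal over the array's 75th percentile (y axis) of Ptk2 (2 probes) and 8 other genes on each of the 12 arrays, in the 4 groups (x axis); open points were not well above background, and bars give the mean ± SD, n = 3. The brighter Ptk2 probe sat between 0.03 and 0.50 in all groups, while Upk3b and Wt1 were above background in KO cells alone and Grem1 and Twist2 in rescue cells alone.

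The first comparison asked which genes differ between KO and rescue cells at the sparse seeding, where cells have few neighbours. Of the genes tested, 48.8% differed. Among the genes with large differences were some that were bright in 1 line and not well above background in the other, such as Wt1 and Twist2, transcription factor genes of different tissues. Lists of matrix, caveolar, cholesterol synthesis and lysosome genes were lower in KO cells by camera with a preset correlation, calls that were lost with an estimated correlation. Of 12438 genes, 6069 changed (limma, 2890 higher and 3179 lower in KO cells), 3937 of them at least 2-fold, and 7321 genes had groups that did not overlap, against 10% by chance. For 330 of the changed genes at least 1 KO array and no rescue array was well above background, and for 456 the reverse held.

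Among the genes higher in sparse KO cells were Upk3b, a uroplakin gene (at least 1300-fold, limma adjusted p = 2.22e-12), and Wt1, a transcription factor gene of kidney and mesothelial development (at least 1570-fold, adjusted p = 1.26e-10). Mest, an imprinted gene, was higher by 11.76 ± 0.27, with 2 of 3 sparse rescue arrays well above background. Gucy1a1 (a subunit of soluble guanylate cyclase) was at least 965-fold higher, Bex2 at least 914-fold and Ptgis (prostacyclin synthase) at least 1070-fold. Lpl, for lipoprotein lipase, was higher by 6.81 ± 0.29, and Abca1, for the transporter that exports cholesterol, at least 42.4-fold (adjusted p = 4.35e-08). Among the genes lower in KO cells were the urea transporter gene Slc14a1 (at least 1720-fold, adjusted p = 7.76e-09) and Grem1, for a secreted BMP antagonist (at least 1620-fold, adjusted p = 3.76e-11). Twist2, a transcription factor gene of mesenchyme, was at least 763-fold lower, and Perp, a p53 target that encodes a desmosome-associated protein, at least 762-fold. Ank, for a pyrophosphate transporter, was at least 351-fold lower and Dpysl3 at least 482-fold. Foxo3 did not pass (adjusted p = 0.149) but did with quantile or median scaling; with 2 of 3 rescue and 0 of 3 KO arrays well above background, it has no fold here.

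Of 23 gene lists fixed beforehand, 5 shifted in sparse cells by camera with a preset correlation, all of them down in KO cells, and none passed with an estimated correlation. Of 51 collagen and matrix genes, 29 were lower, 14 higher and 8 did not pass (14 higher and 31 lower adjusted over the list alone), with a median of -1.26 (camera, adjusted p = 0.0172; adjusted p = 0.355 with an estimated correlation). Postn (periostin) was at least 242-fold lower and Thbs2 (thrombospondin 2) at least 303-fold, while the laminin gene Lama5 was higher by 7.81 ± 0.29. Of 27 cholesterol synthesis and uptake genes, 16 were lower, 2 higher and 9 did not pass (the same counts adjusted over the list alone), with a median of -0.76 (adjusted p = 0.0172; adjusted p = 0.583 with an estimated correlation). The enzyme genes Tm7sf2 (-2.62 ± 0.22), Mvk (-2.47 ± 0.25) and Nsdhl (-2.39 ± 0.19) were lower, and Ggps1 was higher (1.24 ± 0.18). Of 11 caveolar genes, 7 were lower, 0 higher and 4 did not pass (the same adjusted over the list alone), with a median of -1.47 (adjusted p = 0.0172; adjusted p = 0.471 with an estimated correlation). Cavin4 (-5.39 ± 0.41) and Cav2 (-3.12 ± 0.22) were lower.

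Of 39 lysosome and autophagy genes, 21 were lower, 6 higher and 12 did not pass in sparse cells (the same adjusted over the list alone), with a median of -0.69, or -0.66 with undetected genes at their bound (camera, adjusted p = 0.0235; adjusted p = 0.583 with an estimated correlation). Wipi1, for an autophagy protein, was lower, at -2.35 ± 0.17. Of 31 matrix protease and inhibitor genes, 17 were lower, 5 higher and 9 did not pass (the same adjusted over the list alone), with a median of -1.02, or -0.66 with bounds (adjusted p = 0.0491; adjusted p = 0.583 with an estimated correlation). This call was also lost with the slide as a block (median -0.71, adjusted p = 0.0728) and without any of 6 arrays (adjusted p up to 0.0991, without rescue_sparse 3). Adamts2 was lower (-4.11 ± 0.29) and Mmp23 higher (5.15 ± 0.41). Of 43 focal adhesion and integrin genes, 18 were lower, 6 higher and 19 did not pass (the same adjusted over the list alone), and the list did not pass camera (adjusted p = 0.109). The collagen-binding integrin gene Itga11 was at least 57.9-fold lower, and Itga7, for a laminin receptor, was higher by 4.17 ± 0.25. The list of cell cycle genes did not pass either (median 0.19, adjusted p = 0.215), with 16 of 53 higher and 5 lower. It passed with the slide as a block (median 0.36, adjusted p = 0.0303), where the difference between the lines rests on 1 slide. Centring arrays on their median moved the median of all genes by -0.30 and left 2 lists past the test, with all 5 medians still below 0. With normexp the medians of the matrix protein and protease lists were -0.77 and -0.40. Scaling to spike-in RNA gave all 5 lists medians of -3.02 to -2.23. Within the shared slide the medians of the 5 lists were -1.50 to -0.42.

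The same question at the dense seeding gave more differences. In dense KO cells the list of cell cycle genes was higher, and those of interferon-stimulated, lysosome, matrix protease and FOXO target genes were lower, by camera with a preset correlation, calls that were lost with an estimated correlation. Upk3b, Wt1, Grem1 and Perp were again among the extremes. In dense cells 7667 genes changed (limma, 3972 higher and 3695 lower in KO cells), 5482 of them at least 2-fold, and 8352 had groups that did not overlap, against 10% by chance. For 365 changed genes at least 1 KO array and no rescue array was well above background, and for 478 the reverse held. The log2 fold changes of the lines in sparse and dense cells had r = 0.879 and rho = 0.764 across genes, which are not independent replicates. Higher in both were 2199 genes and lower in both 2490, against 922.9 and 944.4 for independent lists, and 146 changed in opposite directions.

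In dense cells Upk3b was at least 2590-fold higher in KO cells (limma, adjusted p = 5.89e-13), Wt1 at least 2130-fold (adjusted p = 1.03e-10) and Gpm6a, for a neuronal membrane glycoprotein, at least 1160-fold (adjusted p = 4.68e-08). Mest was higher by 11.65 ± 0.27. Smpd3, for a sphingomyelinase, was higher by 10.24 ± 0.20, with 2 of 3 dense rescue arrays well above background, Lpl by 6.65 ± 0.29 and Apoe by 4.21 ± 0.29. Grem1 was at least 2270-fold lower (adjusted p = 1.68e-11), Perp at least 2840-fold (adjusted p = 2.36e-10) and Gpnmb, for a glycoprotein of lysosome-related organelles, at least 1160-fold (adjusted p = 7.22e-12). Postn and Thbs2 were at least 633-fold and at least 718-fold lower. Foxo3 was lower, at -1.64 ± 0.27 (adjusted p = 0.000248), with 1 of 3 KO arrays well above background. Abca1 did not pass in dense cells (-0.45 ± 0.38, adjusted p = 0.33; -0.68 to -0.14 without 1 of the arrays).

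Of 53 cell cycle genes, 52 were higher in dense KO cells, 0 lower and 1 not past the test (the same adjusted over the list alone), with a median of 2.18 (camera, adjusted p = 5.3e-14; adjusted p = 0.0961 with an estimated correlation). Ccne2, for a cyclin of the G1/S transition, was higher by 4.53 ± 0.42, the E2F family gene E2f8 by 4.47 ± 0.36 and the S-phase transcription factor gene Mybl2 by 4.42 ± 0.24. Genes of the amino acid response downstream of ATF4 were 23 higher, 5 lower and 10 not past the test of 38 (the same adjusted over the list alone), with a median of 0.96 (adjusted p = 0.0053; adjusted p = 0.169 with an estimated correlation). Among them the hormone gene Fgf21 was higher by 4.77 ± 0.38, with 2 of 3 dense rescue arrays well above background, and Cth (cystathionine gamma-lyase) at least 33.7-fold lower. The unfolded protein response list did not pass (median 0.78, adjusted p = 0.0589). Of its 23 genes 15 were higher, 2 lower and 6 not past the test, the same adjusted over the list alone. It passed with the slide as a block (median 0.76, adjusted p = 0.038), where the difference between the lines rests on 1 slide.

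Of 31 interferon response genes, 25 were lower in dense KO cells, 2 higher and 4 not past the test (the same adjusted over the list alone), with a median of -2.30, or -2.17 with bounds (camera, adjusted p = 1.16e-06; adjusted p = 0.0784 with an estimated correlation). Rtp4 was at least 44.9-fold and Trim30a at least 24.4-fold lower, Gbp2, for an interferon-induced GTPase, was lower, at -6.27 ± 0.47, and Oasl1 was higher by 3.42 ± 0.27. Of 39 lysosome and autophagy genes, 31 were lower, 2 higher and 6 not past the test (the same adjusted over the list alone), with a median of -1.59 (adjusted p = 6.32e-07; adjusted p = 0.0961 with an estimated correlation). Wipi1 (-3.24 ± 0.17), the acid lipase gene Lipa (-3.08 ± 0.24) and the saposin precursor gene Psap (-3.04 ± 0.32) were lower, and Tfeb, for a regulator of lysosomal genes, was higher (1.78 ± 0.29). Of 28 FOXO targets, 18 were lower, 4 higher and 6 not past the test (the same adjusted over the list alone), with a median of -1.17 (adjusted p = 0.00108; adjusted p = 0.137 with an estimated correlation). They included Pik3ip1, for an inhibitor of PI3 kinase (-4.56 ± 0.41), and Sesn3 (-3.78 ± 0.29).

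Of 51 matrix genes, 32 were lower in dense KO cells, 9 higher and 10 not past the test (9 higher and 33 lower adjusted over the list alone), with a median of -1.55 (camera, adjusted p = 0.000135; adjusted p = 0.0782 with an estimated correlation). Matn2 was lower, at -8.99 ± 0.27, and the fibrillin gene Fbn2 at least 75.7-fold higher. Of 31 matrix protease genes, 20 were lower, 2 higher and 9 not past the test (2 higher and 21 lower adjusted over the list alone), with a median of -2.06, or -1.67 with bounds (adjusted p = 0.000119; adjusted p = 0.0961 with an estimated correlation). The stromelysin gene Mmp3 was at least 15-fold and the collagenase gene Mmp13 at least 10.7-fold lower, and Mmp15 at least 10.4-fold higher. Of 27 chemokine and cytokine genes, 17 were lower, 6 higher and 4 not past the test (the same adjusted over the list alone), with a median of -2.33, or -1.02 with bounds (adjusted p = 0.00418; adjusted p = 0.242 with an estimated correlation). Il1rl1, for the receptor of interleukin 33, was at least 97.2-fold lower, Ptgs2, for an inducible prostaglandin synthase, at least 67.8-fold and Ccl8 at least 33-fold, while Cxcl16 was higher by 5.35 ± 0.35, with 2 of 3 dense rescue arrays well above background. Within the shared slide the medians of the 6 lower lists were -2.46 to -1.38. Spike-in scaling moved the medians in dense cells by 0.82, which gave -0.35 for FOXO targets, -0.73 for matrix proteins, -0.77 for lysosome, -1.51 to -1.24 for the other 3 lower lists and 1.79 for the amino acid response. With normexp those of chemokines, proteases and interferon genes were -0.62, -0.998 and -1.49.

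The comparison of densities in rescue cells asked how cells with FAK respond to crowding. Crowded rescue cells had less mRNA of every cell cycle gene measured, and less for amino acid supply and, in calls that were lost with an estimated correlation, the contractile cytoskeleton and YAP targets. They had more mRNA for lysosomes, interferon-stimulated genes, FOXO targets and matrix proteins. In rescue cells 4978 genes changed (limma, 2366 higher and 2612 lower at the dense seeding), 2884 of them at least 2-fold, and 6299 had groups that did not overlap, against 10% by chance. Abca1 was at least 78-fold higher in dense cells (adjusted p = 7.85e-07). Selenop, for a selenium transport protein, rose by 7.33 ± 0.49 (adjusted p = 1.88e-06), with 1 of 3 sparse arrays well above background, and Enpp2, for the enzyme autotaxin, by 5.47 ± 0.37 (adjusted p = 1.88e-06). The small leucine-rich proteoglycan genes Lum (at least 11.3-fold) and Prelp (5.25 ± 0.43) rose too. Cyp1a1, a target of the aryl hydrocarbon receptor, fell at least 10.2-fold (adjusted p = 2.92e-05) and the cornified envelope gene Lce1f at least 20.1-fold. Lce1g fell by 6.67 ± 0.61, but without rescue_sparse 1 another probe of the gene passed the filter and gave 0.26. Ptk2b did not pass (0.62 ± 0.32, adjusted p = 0.143; 0.26 without rescue_sparse 1), and Foxo3 rose by 0.93 ± 0.27 (adjusted p = 0.0182), a call that was lost without rescue_dense 2 (0.70) or rescue_sparse 1.

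All 53 cell cycle genes fell in crowded rescue cells (the same adjusted over the list alone), with a median of -2.03 (camera, adjusted p = 3.28e-23), and this call held with an estimated correlation, as did those of the lysosome, interferon, amino acid response, FOXO and matrix lists. Mybl2 fell by 3.86 ± 0.24, the replication licensing gene Cdc6 by 3.42 ± 0.24 and Ccne2 by 3.30 ± 0.42. Of 38 amino acid response genes, 26 fell, 2 rose and 10 did not pass (3 higher and 27 lower adjusted over the list alone), with a median of -1.10 (adjusted p = 5.77e-07). They included Slc7a11, for the cystine importer (-3.46 ± 0.46, 1 of 3 dense arrays well above background), and the mitochondrial folate enzyme gene Mthfd2 (-3.09 ± 0.25), while Nupr1 rose by 1.17 ± 0.17. Of 39 lysosome genes, 27 rose, 0 fell and 12 did not pass (28 and 0 adjusted over the list alone), with a median of 1.04 (adjusted p = 4.1e-10). The cathepsin gene Ctsf rose by 2.22 ± 0.26 and the glycosidase gene Naglu by 1.91 ± 0.24.

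Of 31 interferon response genes, 24 rose in crowded rescue cells, 1 fell and 6 did not pass (the same adjusted over the list alone), with a median of 1.60, or 1.11 with bounds (camera, adjusted p = 5.3e-10). Oasl2 rose by 4.72 ± 0.29, with 1 of 3 sparse arrays well above background, Ifit3 by 3.84 ± 0.16 and Ifit1 at least 5.58-fold. Of 28 FOXO targets, 17 rose, 1 fell and 10 did not pass (19 and 1 adjusted over the list alone), with a median of 0.93 (adjusted p = 2.68e-06). Pik3ip1 rose by 4.38 ± 0.41, Klhl24 by 3.50 ± 0.27 and the muscle ubiquitin ligase gene Trim63 at least 4.92-fold. Of 51 matrix genes, 23 rose, 5 fell and 23 did not pass (the same adjusted over the list alone), with a median of 0.69 (adjusted p = 0.000575). Dcn (decorin) rose by 4.55 ± 0.26 and Mgp, for an inhibitor of calcification, by 4.06 ± 0.33. The matrix protease list was also higher, with 13 genes up, 6 down and 12 not past the test (14 and 6 adjusted over the list alone), a median of 0.98, or 0.92 with bounds (adjusted p = 0.0108), and adjusted p = 0.178 with an estimated correlation. Mmp13 rose at least 11.6-fold and Mmp3 at least 15.8-fold.

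The remaining lists that passed in rescue cells were lost with an estimated correlation. Of 31 SRF and actomyosin genes, 16 fell, 2 rose and 13 did not pass (2 higher and 17 lower adjusted over the list alone), with a median of -0.71 (camera, adjusted p = 0.00125; adjusted p = 0.178 with an estimated correlation), which scaling to spike-in RNA turned to 0.01. The smooth muscle genes Cnn1 (-2.04 ± 0.20) and Actg2 (-1.86 ± 0.32) fell, and Csrp2 rose (1.39 ± 0.18). Of 27 YAP and TEAD targets, 16 fell, 5 rose and 6 did not pass (the same adjusted over the list alone), with a median of -1.01, or -0.88 with bounds (adjusted p = 0.0117; adjusted p = 0.182 with an estimated correlation). The classical targets Ccn2 (-3.19 ± 0.34) and Ankrd1 (-3.01 ± 0.35) fell. Of 23 LXR targets and sterol efflux genes, 12 rose, 3 fell and 8 did not pass (the same adjusted over the list alone), with a median of 0.81 (adjusted p = 0.0108; adjusted p = 0.168 with an estimated correlation). Besides Abca1 they included Tgm2, for a transglutaminase (1.90 ± 0.24), while Rgs16 fell at least 5.85-fold. The 2 arrays of a day were on 1 slide here. Spike-in scaling moved these medians by 0.72, to -1.31 for cell cycle, -0.38 for amino acid response and -0.29 for YAP targets, and 1.41 to 2.33 for the lists that rose. With normexp those of interferon, protease and YAP genes were 0.75, 0.52 and -0.55.

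**Figure D2:**
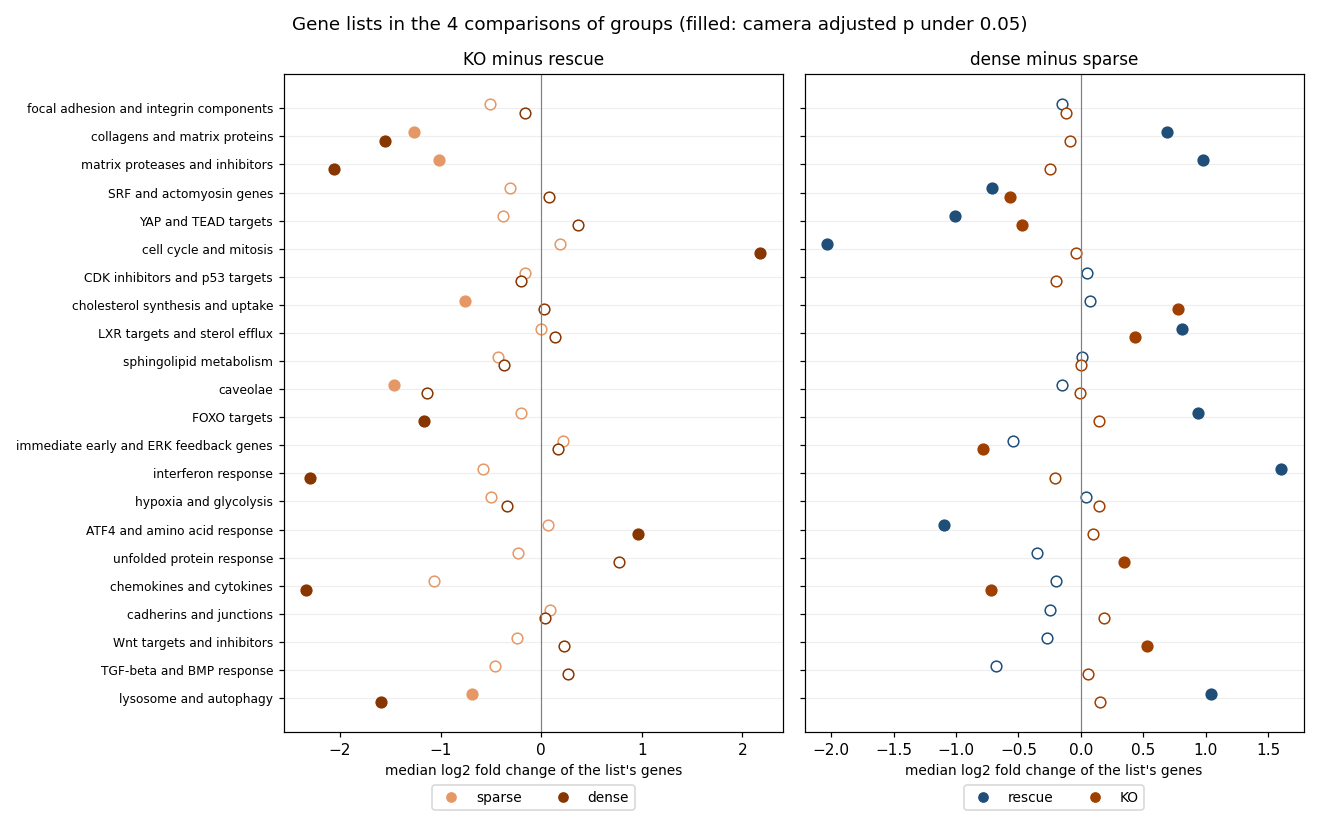
Median log2 fold change (x axis) of the genes of each of 22 of the 23 lists (y axis), KO minus rescue in sparse and dense cells (left) and dense minus sparse in rescue and KO cells (right); filled points passed camera with the preset correlation. Cell cycle genes had a median of 2.18 between the lines in dense cells, -2.03 with density in rescue cells and -0.04 with density in KO cells; of the lists that passed, scaling to spike-in RNA turned the median of SRF genes above 0 in both density comparisons, and in KO cells those of YAP targets, immediate early genes and chemokines.

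The comparison of densities in KO cells asked what remains of the response to crowding without FAK. Fewer genes passed than in rescue cells with the 75th percentile as the scale. More passed with spike-in scaling (12382 in KO and 3432 in rescue cells). Cholesterol synthesis genes were higher in crowded KO cells, and immediate early, actomyosin and chemokine genes were lower, as lists by camera with a preset correlation; none of these calls held with an estimated correlation, and the cell cycle list did not pass. In KO cells 1358 genes changed (limma, 676 higher and 682 lower at the dense seeding), 768 of them at least 2-fold, 3374 had an unadjusted p under 0.05, and 4747 had groups that did not overlap, against 10% by chance. The count depended on single cultures: 514 genes without KO_dense 2, 601 without KO_sparse 1, 672 without KO_sparse 3 and 881 without KO_dense 1. It was 0 without day 1 (limma, 2002 genes with an unadjusted p under 0.05), 260 without day 2 and 622 without day 3. Of the 87 genes eligible for naming in this comparison, 42 changed in call or size without 1 of the arrays, against 11 of 91 for density in rescue cells. Most genes named below for KO cells were among those that did not, so they look firmer than the eligible genes as a whole. Directions are relative to the other genes of an array: median centring moved the median of all genes by 0.25, and spike-in scaling by 3.10, after which 12380 of the called genes were higher in dense cells.

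Dhrs3, for a retinal reductase, rose by 3.34 ± 0.48 in crowded KO cells (limma, adjusted p = 0.00268), the elastin gene Eln by 3.12 ± 0.49 (adjusted p = 0.00376) and Parvb, for an adhesion adaptor, by 3.06 ± 0.44 (adjusted p = 0.00258), with 1 of 3 sparse arrays well above background. The largest fitted rises, of Syt10 (6.41 ± 1.85, adjusted p = 0.0472) and Prm1 (3.85 ± 0.95, adjusted p = 0.0256), were less firm. Syt10 lost its call without any of 8 of the 12 arrays (5.53 to 7.95), and Prm1 gave -0.09 without KO_dense 1, when another probe of the gene took over. The largest fall was that of Rn28s1, a 28S ribosomal RNA and not an mRNA (-6.02 ± 1.18, adjusted p = 0.00945). Fosl1, for the AP-1 subunit Fra-1, fell by 4.48 ± 0.51 (adjusted p = 0.00129), with 2 of 3 dense arrays well above background, the kinase gene Sgk1 by 3.10 ± 0.28 (adjusted p = 0.000717) and the phosphatase gene Ptpn22 at least 5.01-fold (adjusted p = 0.00175). Abca1 (0.43 ± 0.38, adjusted p = 0.507; 0.26 to 0.67 without 1 of the arrays) and Ptk2b (1.01 ± 0.32, adjusted p = 0.0635) did not pass, and neither did Foxo3 (adjusted p = 0.683), with 0 of 3 sparse and 1 of 3 dense arrays well above background.

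Of 27 cholesterol synthesis and uptake genes, 14 rose in crowded KO cells, 0 fell and 13 did not pass (20 higher and 1 lower adjusted over the list alone), with a median of 0.78 (camera, adjusted p = 2.93e-10; adjusted p = 0.0821 with an estimated correlation). The farnesyl diphosphate synthase gene Fdps rose by 1.95 ± 0.24, Lpin1 by 1.66 ± 0.28 and Tm7sf2 by 1.63 ± 0.22. Of 23 LXR targets, 6 rose, 0 fell and 17 did not pass (8 and 0 adjusted over the list alone), with a median of 0.43 (adjusted p = 0.000401; adjusted p = 0.0821 with an estimated correlation), and Tgm2 rose by 2.11 ± 0.24. Of 23 unfolded protein response genes, 4 rose, 0 fell and 19 did not pass (9 and 0 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.000992; adjusted p = 0.0821 with an estimated correlation). Derl3, for a protein of endoplasmic reticulum degradation, rose by 2.38 ± 0.36. Of 26 Wnt targets and inhibitors, 3 rose, 0 fell and 23 did not pass (7 higher and 2 lower adjusted over the list alone), with a median of 0.53, or 0.44 with bounds (adjusted p = 0.0242; adjusted p = 0.238 with an estimated correlation; adjusted p = 0.0979 without KO_sparse 1). Spike-in scaling gave these 4 lists medians of 3.44 to 3.88. Median centring gave the LXR and unfolded protein lists 0.68 and 0.60, quantile scaling gave the latter 0.55, and normexp gave the LXR and Wnt lists 0.26 and 0.30.

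Of 30 immediate early and ERK feedback genes, 14 fell in crowded KO cells, 0 rose and 16 did not pass (1 higher and 19 lower adjusted over the list alone), with a median of -0.78 (camera, adjusted p = 4.13e-08; adjusted p = 0.0821 with an estimated correlation). After Fosl1, Myc (-2.20 ± 0.36) and the phosphatase gene Dusp2 (-1.89 ± 0.21) fell most. Of 31 SRF and actomyosin genes, 7 fell, 0 rose and 24 did not pass (1 higher and 11 lower adjusted over the list alone), with a median of -0.57 (adjusted p = 5.86e-07; adjusted p = 0.0821 with an estimated correlation), among them Actb, for beta-actin (-1.78 ± 0.33). Of 27 YAP and TEAD targets, 7 fell, 1 rose and 19 did not pass (2 higher and 11 lower adjusted over the list alone), with a median of -0.48, or -0.43 with bounds (adjusted p = 0.000401; adjusted p = 0.097 with an estimated correlation). Ankrd1 (-2.51 ± 0.35) and Ccn2 (-1.76 ± 0.34) fell, as in rescue cells, and Igfbp3 rose (1.46 ± 0.27). Of 27 chemokine and cytokine genes, 12 fell, 2 rose and 13 did not pass (2 higher and 13 lower adjusted over the list alone), with a median of -0.72, or -0.47 with bounds (adjusted p = 6.95e-06; adjusted p = 0.0958 with an estimated correlation). Ccl20 (-2.78 ± 0.47), Il6 (-2.77 ± 0.28, 1 of 3 dense arrays well above background) and Ccl7 (-2.56 ± 0.42) fell, and Il33 rose (1.39 ± 0.24). Spike-in scaling turned the medians of these 4 lists to 2.32 to 2.62. That of chemokines was -0.09 with normexp, -0.46 with quantile scaling and -0.47 with median centring. That of YAP targets -0.26 with normexp and -0.22 with median centring, and that of SRF genes -0.32 with median centring. Of 53 cell cycle genes, only Hmmr fell (-1.54 ± 0.43), a call lost without any of 10 arrays (-1.92 to -1.01), and 0 passed limma adjusted over the list alone; the list's median was -0.04, its mean -0.01 and camera's direction up (adjusted p = 0.887).

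The interaction asked whether the lines respond to density in different ways, and so also whether the differences between the lines depend on density. By camera the lists of cell cycle, amino acid response (22 of 38 genes passed upward) and unfolded protein response genes (8 of 23) shifted upward, more positive with crowding in KO than in rescue cells. Those of interferon (17 of 31 genes passed downward), FOXO (9 of 28), lysosome (16 of 39) and matrix protein genes (12 of 51, and 4 upward) shifted downward, with medians that spike-in scaling (a shift of 2.37) turned above 0. With an estimated correlation the calls of the lysosome and matrix protein lists were lost (adjusted p = 0.0506 for both). The test passed for 2579 genes (limma, 1402 with a more positive and 1177 with a more negative change in KO cells). Single genes, such as Abca1 (its change with density at least 57.9-fold lower in KO cells, adjusted p = 3.05e-05), are given with the results that differ between groups. Of 53 cell cycle genes 45 passed upward, 0 downward and 8 did not pass (49 and 0 adjusted over the list alone), with a median of 2.01 (camera, adjusted p = 1.49e-25), a call that held with an estimated correlation. Density responses in the lines had r = 0.265 and rho = 0.265 across genes, which are not independent replicates. In both lines 334 genes rose and 290 fell, against 128.6 and 143.2 for independent lists, and 118 changed in opposite directions. Without 1 of the days the count was 920 to 1214.

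**Figure D3:**
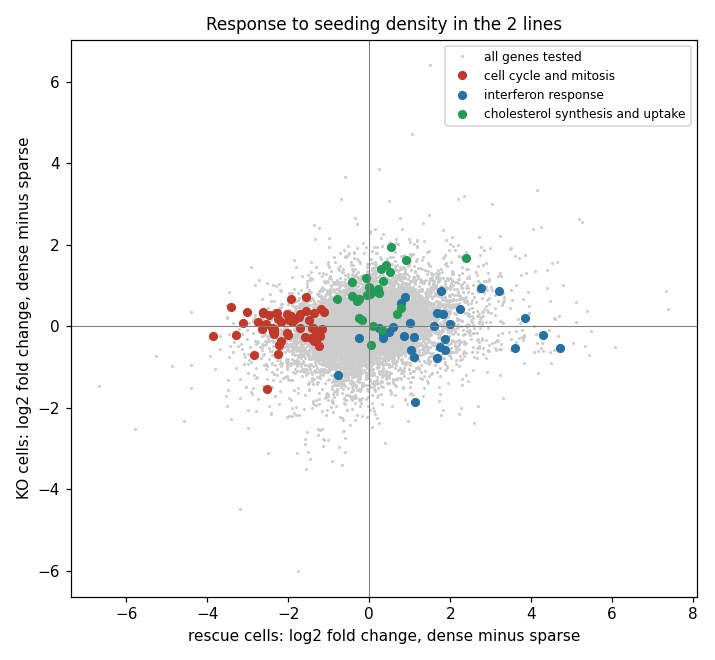
Log2 fold change of each of 12438 genes with density in rescue cells (x axis) and in KO cells (y axis), with cell cycle, interferon response and cholesterol genes coloured; grey points are the other genes and the lines mark a change of 0. Cell cycle genes had a median of -2.03 in rescue and -0.04 in KO cells, interferon response genes 1.60 and -0.20, and cholesterol genes 0.08 and 0.78, before scaling to spike-in RNA, which added 0.72 in rescue and 3.10 in KO cells.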

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

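The mesothelial test, the test of cell cycle genes at the sparse seeding, the ratios on left-out days and the splits that part every day pair were chosen after the result was seen. The results here differ between the lines in how they respond to density, by limma's interaction test. It passed for 2579 of 12438 genes (1402 more positive and 1177 more negative in KO cells). In 100 splits of density drawn within each line (200 are possible), 4 called as many genes, the real one included, a share under 0.05. Among the 32 splits that part every day pair, as the real one does, 3 did (a share of 0.0938, highest other 4741). Moving arrays between densities also breaks up the density response of each line, not only the difference between the lines. These shares therefore cannot tell whether the interaction arose by chance. Without 1 of the days 920 to 1214 genes passed. The highest of the other splits (4741 genes) keeps the density groups of both lines with the labels of 1 line exchanged, and the next (3022 and 2757) keep the rescue groups with 2 KO arrays moved, which points to the large density response of rescue cells as a structure of the samples.

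Of single genes, Abca1, for a cholesterol exporter, rose at least 78-fold with density in rescue cells, where no sparse array was well above background, and was well above background on all KO arrays, so that its change with density was at least 57.9-fold lower in KO cells (limma interaction, 3 cultures per group, adjusted p = 3.05e-05). Selenop had an interaction of -6.48 ± 0.69 (log2 ± SE), with 1 of 3 sparse rescue arrays well above background, and the change of Islr was at least 25-fold lower, but without rescue_dense 3 another probe of the gene took over and gave -0.24. For Cobl, for an actin nucleator, and Fst, for the activin antagonist follistatin, neither well above background in dense rescue cells, it was at least 20.6-fold and at least 12.8-fold higher in KO cells. Lce1g had 5.20 ± 0.86, but 0.42 without rescue_sparse 1 with probes chosen again. S100g, Lum, Lce1f and Cxcr6 passed too but were not well above background on any KO array, so that their interactions compare a change in rescue cells with background and have no bound. The fitted interactions of these genes with a group at background rest on that signal and are not sizes: Abca1 -6.96, Islr -5.83, Cobl 4.77, Fst 4.38, S100g -6.58, Lum -6.14, Lce1f 4.54 and Cxcr6 4.28.

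Of the lists, 10 of 23 and 2 of the 9 cell type lists passed camera for the interaction; the medians follow, with counts of genes more positive, more negative and not past the test in KO cells. Upward were cell cycle (2.01; 45, 0 and 8; 49 and 0 adjusted over the list alone), the ATF4 and amino acid response (1.101; 22, 1 and 15; 25 and 2), the unfolded protein response (0.90; 8, 0 and 15; 8 and 0) and cholesterol synthesis (0.76; 8, 0 and 19; 9 and 0). Downward were the interferon response (-1.60; 0, 17 and 14; 0 and 21), chemokines and cytokines (-1.12; 2, 9 and 16; 2 and 10), matrix proteases (-0.96; 3, 11 and 17; 3 and 11), lysosome (-0.89; 0, 16 and 23; 0 and 22), FOXO targets (-0.78; 0, 9 and 19; 0 and 10) and matrix proteins (-0.49; 4, 12 and 35; 4 and 13). With an estimated correlation the calls of cell cycle (adjusted p = 0.0264), interferon (0.0243), ATF4 (0.0264), unfolded protein response (0.0264) and FOXO (0.0449) held, and those of cholesterol (0.251), lysosome (0.0506), proteases (0.073), matrix proteins (0.0506) and chemokines (0.251) did not. The epithelial list (1.05; 4, 0 and 9, the same adjusted over the list alone) had adjusted p = 0.301 with an estimated correlation and lost its call without any of 4 arrays (adjusted p up to 0.0684, without rescue_dense 2). The sex chromosome list (-1.83; 0, 3 and 1, the same adjusted over the list alone) had adjusted p = 0.236 with an estimated correlation and compares rescue values with background; its median was -0.59 with normexp and -1.16 with genes at their bounds. Spike-in scaling adds 2.37 to every interaction and turned the medians of all downward lists above 0 (0.54 to 1.88). With normexp the medians were -0.76 for interferon, -0.31 for chemokines, -0.46 for proteases and 0.27 for the epithelial list, with median centring -0.24 for matrix proteins, and with genes at their bounds -1.52 for interferon, -0.80 for chemokines and -0.92 for proteases.

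The first pattern weighed is that density changed fewer genes in KO cells (1358) than in rescue cells (4978), which holds for scaling to the 75th percentile. Spike-in scaling turned these counts round (12382 and 3432), as it added 3.10 to every density change in KO cells. Nearly all genes called in KO cells were then higher. That count therefore does not show how many genes changed relative to the other genes of an array. Lower power is argued against, since among 4200 genes called in rescue cells and well above background on every array the median ratio of the KO to the rescue change was 0.21 (quartiles -0.07 and 0.48), and the median SD between replicates was lower in KO cells (0.179 and 0.216) than in rescue cells (0.271 and 0.247). Being called in rescue cells lowers this ratio by itself (among 1113 genes called in KO cells the converse ratio was 0.57), but with genes called on 2 days and median changes taken from the day left out it was 0.27, 0.25 and 0.09, with a converse of 0.14 without day 2 (150 genes) and 1.07 without day 3 (474 genes), and no gene called in KO cells by limma without day 1. Silence of these genes in the KO line is argued against too, since 5.24% of the genes called in rescue cells were not above background on any KO array. A lower growth state of sparse KO cells is not what the cell cycle list shows. Its median was 0.19 between the lines at the sparse seeding, against -2.03 for density in rescue cells. With the slide as a block, where the difference between the lines rests on 1 slide, that median was 0.36. What remains open, and was not tested, is FAK itself, the different media, and other differences between the lines.

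The second pattern is that 6069 and 7667 genes differed between the lines. A slide effect is argued against, since 98.2% of the genes called in both densities on the other 4 slides had the same sign in both densities on the slide that held both lines. Lines of different origin, or loss or silencing of Y-linked genes in the KO line, may account for part of it. The 3 sex-linked genes Ddx3y (at least 55.2-fold higher in rescue cells), Kdm5d (at least 18-fold) and Eif2s3y (at least 48-fold) were well above background on all 6 rescue arrays and no KO array. Y-linked Uty was so on 3 rescue arrays and Usp9y and Sry on 1 each, all on no KO array. Zfy1 and Xist were so on no array. Zfy2 was the only Y-linked gene looked at that was well above background on any KO array. It was so on all 12 arrays (means of -3.40 in rescue and -3.67 in KO cells), which goes against loss of the whole chromosome if its probe is specific. Loss or silencing of chromosome segments may add to it, as 19 neighbouring pairs (next to each other by start position in the supplied gene table, among 10869 genes well above background on all rescue arrays) lay among 253 genes silent in the KO line, against 5.89 in random draws (2 to 11; permutation p = 0.0001, the smallest that the draws can give), although neighbouring family members, such as Trim12c, Trim30a and Trim30d (named after their values were seen), can share regulation, and the rescue line had 13 such pairs against 3.11. A mesothelial-like KO line and a fibroblast-like rescue line is a candidate explanation. Of 18 mesothelial genes listed, 15 were tested, all well above background on every KO array, and a gene dim in all groups could not enter. Their medians were 4.28 in sparse and 5.49 in dense cells (4.28 and 3.97 with bounds). In sparse cells 11 were higher and 1 lower, and in dense cells 13 and 1. But Msln was lower (-1.31 and -1.66), 4 genes are also in the epithelial list, and 11 were well above background on all rescue arrays. Of 13 fibroblast markers tested, 11 were well above background on all KO arrays and 12 on all rescue arrays. An effect of FAK was not tested apart from these explanations.

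With 3 against 3 cultures there are 10 splits, too few for a share under 0.05. The real split, 1 of the 10, called 6069, 7667, 4978 and 1358 genes in the first 4 comparisons, and the highest of the others called 0, 0, 1 and 12. The splits that part as many day pairs as the real one called at most 0, 0, 0 and 3 genes.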

How the results depend on the processing

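Normexp on median signals, the slide as a random block, probes without a gene, spike-in scaling, the deposited table for days 1 and 2, and filter and probes chosen again were chosen after seeing the data; the planned normexp on mean signals was not run. Of 403 values of the leading results (counts, Ptk2 and numbers of lists) outside the deposited table and without probes chosen again, 367 stayed the same, 29 were weaker and 7 stronger. For counts and numbers of lists this means within, below or above a set ratio to the main count. For Ptk2 it means a kept, lost or gained call, and for correlations between comparisons a kept sign. Of 13243 values of named genes 12558 kept their direction and side of the threshold, 670 lost and 14 gained a call and 1 reversed. Of 1428 values of lists 1257 kept both, 72 lost and 98 gained a call and 1 reversed. With filter and probes chosen again, 249 of 266 leading values stayed the same and 17 were weaker. Of 8569 values of named genes 8019 then kept their direction and side of the threshold and 3 reversed. The cause of a change was not tested, except that fewer arrays, a stricter threshold and other probes change results by construction.

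Leaving out arrays or days, with probes held or chosen again, gave 3090 to 5158 genes for density in rescue cells, 0 to 1599 in KO cells (0 by limma without day 1, with 2002 genes at an unadjusted p under 0.05), 920 to 2572 for the interaction, and -1.08 to -0.68 for the other Ptk2 probe between the lines in dense cells. That probe also lost its call with normexp (-0.40, adjusted p = 0.122, also with probes chosen again) and with the slide as a block (-0.53, adjusted p = 0.123). An adjusted p under 0.01 left 4492 genes between the lines in sparse cells, 3255 and 393 for density in rescue and KO cells and 1202 for the interaction, and a 2-fold minimum 3937 genes between the lines in sparse cells and 2884 and 768 for density in rescue and KO cells. Including probes without a gene gave 9239 genes between the lines in sparse cells.

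With the day as a replicate block the counts were 6418, 7973, 5364, 1597 and 2950 in the order of the report, and with the slide as a block 4413, 6436, 5249, 1388 and 2792. The slide block takes the mean difference between the lines from 1 slide only. Directions depend on scaling: median centring moved the median of all genes by -0.30 between the lines in sparse cells, 0.25 for density in KO cells and 0.25 for the interaction, with 30.6, 80.9 and 70.9% of called genes higher, and left 2 lists between the lines in sparse cells (also with probes chosen again). Spike-in scaling moved it by -1.55, 0.82, 0.72, 3.10 and 2.37 and gave 9465, 6948, 3432, 12382 and 10805 genes. Numbers of lists fell to 0, 0, 6, 0 and 5 with an estimated correlation and rose to 18, 16 and 17 in the first 3 comparisons with fry, which tests each list on its own.

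In the deposited table the 4 columns of day 3 had their highest correlation with the array of the other line at the same density (0.97 to 0.98, against 0.83 to 0.87 with their own). The scanner arrays of that day lay with their own line, so these columns appear to be exchanged between the lines. Group means of the full table then mix the lines, and its counts and reversals cannot be read as an effect of processing. By limma the full table gave 0, 0, 0, 1 and 0 genes (83, 61, 903, 955 and 32 at an unadjusted p under 0.05), -0.44 and -0.27 for the other Ptk2 probe in sparse and dense cells, and 2 lists between the lines in sparse cells and 6 for the interaction. Days 1 and 2 of the table gave 775 genes for density in KO cells and 1402 for the interaction (772 and 1394 with probes chosen again). Reversed in the table were Aldoc with density in rescue cells (0.10), Stc2 for the interaction (-0.10), and with density in KO cells the lists of cell cycle (-0.62) and ATF4 targets (-0.28).

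Elsewhere, the mean of a gene's probes gave Ptk2 -0.67 with density in rescue cells, and fry gave neural and glial markers between the lines in sparse cells a direction up (median -0.42, adjusted p = 0.0453). With other probes taking over, Islr gave 0.57 for the interaction in days 1 and 2 of the table, Lce1g -7.27 to 0.26 with density in rescue cells and Prm1 -0.089 to 4.88 in KO cells when arrays or days were left out. Signal over background limits small changes in dim genes: 58 to 843 of the changed genes had 1 group with no array well above background.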

Other observations

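Both tests of the spike-in pattern were chosen after the result was seen. Spike-in RNA, added at labelling, had a log2 signal over the array's 75th percentile of 3.54 ± 0.68 (SD, n = 3) in sparse KO cells, 0.44 ± 0.16 in dense KO cells, 1.99 ± 0.36 in sparse rescue cells and 1.26 ± 0.42 in dense rescue cells. In KO cells the sparse arrays were higher by 3.10 ± 0.54 (n = 3 days), and by at least 2.49 within every slide, which argues against a slide effect. The probe of 28S ribosomal RNA differed the same way in KO cells, by 6.02 ± 0.47, on all 3 days. Less RNA of the same composition having been labelled would leave ratios within an array as they are, so this probe argues against it in KO cells. The argument rests on this 1 probe. In dense rescue cells its signal ran from 0.12 to 6.52, against 0.86 to 1.70 for the spike-ins. A sparse sample with proportionally more ribosomal RNA and less mRNA could raise both signals (a hypothesis, and no further test was run). It was not shown to account for their sizes, since 28S differed by more than the spike-ins (6.02 against 3.10). Under spike-in scaling 12382 genes changed with density in KO cells. That scaling would show amounts per input of RNA only if all samples had equal spike-in per input, which was not checked. In rescue cells 28S had 4.97 ± 0.22 in sparse and 3.20 ± 3.20 in dense cells, a spread too wide to compare.

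Of the marker lists of cell types, the fibroblast list was lower in KO cells, with 9 of 13 genes lower, 3 higher and 1 not past the test in sparse cells (median -1.92, camera, adjusted p = 0.0261; adjusted p = 0.0868 with an estimated correlation) and 11 lower, 1 higher and 1 not past the test in dense cells (median -1.90, adjusted p = 0.000898; adjusted p = 0.0313 with an estimated correlation), the same counts adjusted over the list alone. The epithelial list was higher in dense KO cells, with 7 of 13 genes higher, 2 lower and 4 not past the test (8 and 2 adjusted over the list alone; median 1.80, or 1.44 with bounds; adjusted p = 0.0487; adjusted p = 0.265 with an estimated correlation), a call lost without any of 6 arrays (adjusted p up to 0.0674, without KO_dense 1). In sparse cells it did not pass (median 0.41, adjusted p = 0.21) but did with the slide as a block (median 0.51, adjusted p = 0.038). There the difference between the lines rests on 1 slide. The sex chromosome list was lower in KO cells in sparse cells (0, 3 and 1 of 4 genes higher, lower and not past the test; median -5.64, or -4.02 with bounds; adjusted p = 0.00621; adjusted p = 0.0868 with an estimated correlation) and in dense cells (0, 4 and 0; median -7.35, or -5.68 with bounds; adjusted p = 0.000898; adjusted p = 0.0468 with an estimated correlation). The lists of macrophage and haematopoietic (lowest adjusted p of the 5 comparisons 0.137), endothelial (0.177), adipocyte (0.656), bone and cartilage (0.0565), skeletal muscle (0.0824) and neural and glial markers (0.337) passed in no comparison. With normexp the sex chromosome list had medians of -1.77 and -2.52 and the epithelial list 0.57 in dense cells. Skeletal muscle markers passed in dense cells between the lines with the slide as a block (median 1.09, adjusted p = 0.0195), which again rests on 1 slide for the lines.

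Of the 23 gene lists, 7 passed in no comparison, 6 of them described here: focal adhesion and integrin components (lowest adjusted p by camera 0.109), CDK inhibitors and p53 targets (0.0815), sphingolipid metabolism (0.0944), hypoxia and glycolysis (0.0599), cadherins and junctions (0.169) and TGF-beta and BMP response (0.0618). Their single genes changed in both directions: in dense cells between the lines, Smpd3 and B4galnt1 of the sphingolipid list differed by 10.24 and -4.09, Aldoc and Bnip3 of the hypoxia list by 6.00 and -5.27. Medians, means and the direction of camera differed in sign for some lists that did not pass. In sparse cells between the lines, ATF4 targets had a median of 0.07 and a mean of -0.23, cadherins 0.09 and -0.45, Wnt targets -0.24 and 0.44. In dense cells SRF genes had 0.08 and -0.33, YAP targets 0.37 and -0.06, immediate early genes 0.17 and -0.19, cholesterol genes 0.03 and -0.11, and cadherins 0.04 and -0.15; LXR targets had a median of 0.13 and a direction down. With density, Wnt targets (-0.27 and 0.18) and hypoxia genes (0.04 and -0.04) differed in rescue cells, and matrix proteins (-0.09 and 0.10), sphingolipid genes (-0.001 and 0.019), caveolae (-0.01 and 0.04) and TGF-beta targets (0.06 and -0.14) in KO cells. For the interaction, CDK inhibitors (0.05 and -0.33) and immediate early genes (0.01 and -0.28) differed. Of the cell type lists, macrophage markers (0.05 and -0.94 between the lines in sparse cells, -0.11 and 0.41 with density in rescue cells), and in KO cells with density skeletal muscle (-0.43 and 0.14) and adipocyte markers (-0.03, with a direction up) did.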
